A study of Arabidopsis thaliana with 6 samples.

How the data were processed

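RNA from whole shoots of WT and 35S::KLU seedlings was hybridised to single-colour Affymetrix ATH1 arrays, 1 array per sample and 3 samples per genotype. Per the labels, the plants grew on plates with 16 h of light and 8 h of dark at 21 °C, and per the series' design text 1 µg of RNA was used per sample. The deposited table held 1 log2 value per probe set and array, and RMA, which corrects background, quantile normalizes the arrays and summarises the probes of a set, is named in the submitters' processing notes with no version given. The log2 scale of the deposited values was checked from their range, with array medians between 6.01 and 6.05. RMA values compress small signals, so folds of dim probe sets are understated. No detection calls were used here. How evenly the labelling captured transcripts encoded in plastids and mitochondria was not checked. Each array was matched to its genotype and replicate by its label.

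Of 22810 probe sets, 64 Affymetrix control probe sets were left out, and the other 22746 were tested with no filter on level. Probe sets were named from the platform annotation, with 13513 paired with 1 gene, 503 with several and 8730 with none listed. Genes were named only from probe sets with 1 gene, of which 13436 matched the RefSeq gene table of assembly TAIR10.1 and 77 kept the annotation's name. The 13513 probe sets stood for 13356 genes, and 146 genes had several. Gene positions are not given, since no genome build is named for the files. The overexpressed gene KLU had 0 probe sets paired with it and was not analysed here. ARR16 is listed in the annotation as RR16, and the MCM7 gene as PRL.

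Differences were 35S::KLU minus WT on the deposited log2 values, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over all 6 arrays, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Every adjusted p of a gene or probe set comes from this fit unless another setting is named, and every ± is an SD over 3 arrays. Gene lists were tested with limma's camera with a preset correlation of 0.01, on the brightest probe set of each gene, for lists with at least 5 measured genes, adjusted over the lists tested together. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. On simulated data with the real means and spreads, 200 of 22746 probe sets were changed, and limma recovered 52.2% of those changed by 0.5, 92.5% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 3 false calls. In a separate simulation of 41 lists, camera found the 1 list of 15 genes raised by 0.3 and 0 others. The simulated genes were drawn independently, so this does not show how camera behaves on lists of correlated genes.

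The comparison, the 23 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Under the rule, measured CYP78A genes were named first, then the 10 largest rises and 10 largest falls among single-gene probe sets past the threshold whose genotypes did not overlap, then up to 4 members of each fixed list with the smallest unadjusted p. A gene with several probe sets was named by the brightest one. The fixed lists were the CYP78A family, mitosis and cytokinesis, DNA replication, organ size regulators, shoot meristem, cytokinin response, auxin response, abscisic acid with drought and cold, salicylic acid and defence, jasmonate, touch and wound response, heat shock, light harvesting, cytosolic ribosomal proteins, circadian clock, senescence, flavonoid and anthocyanin synthesis, expansins and xyloglucan hydrolases, cuticle, iron deficiency, aliphatic glucosinolates, root markers, and floral genes. Because only 49 of their 376 members had a listed probe set, 26 lists were added after the annotation was seen and before any difference was computed, 25 of them large enough to test, of which 1 is not reported here. Members named from the added lists were chosen after their values were seen. A list of CC-type glutaredoxin genes and one of genes induced in the dark or by sugar starvation were drawn up after the largest differences had been seen.

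The alternatives were 3 other scalings of the deposited values (median-centring, quantile and cyclic loess normalization), array quality weights, the replicate number as a block, leaving out each array in turn, a filter on dim probe sets, other eBayes settings, other thresholds, 1 probe set per gene, the mean of a gene's probe sets, and, for lists, camera with an estimated correlation and fry.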

Results

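Shoots of Arabidopsis thaliana seedlings of the Col-0 accession were profiled on Affymetrix ATH1 arrays, on which a probe set is the group of short probes that reports 1 transcript. The 2 genotypes were the wild type (WT) and 35S::KLU, a line carrying the KLU gene behind the strong and nearly constitutive 35S promoter. KLU encodes the cytochrome P450 monooxygenase CYP78A5, which promotes organ growth. Each genotype had 3 arrays, labelled as biological replicates and, per the series' design text, taken from 3 independent experiments with both genotypes sharing plates. The seedlings were at growth stage 1.03, and each sample pooled 5 of them. The number of arrays limits the precision of every value below. The single comparison asked which transcripts differ when KLU is overexpressed.

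The level of KLU itself was not analysed here, because 0 of the 22746 probe sets tested were paired with it in the annotation used, so the genotype labels were not checked against the transgene. A probe set that reports KLU may be among the 8730 with no listed gene. Of 6 listed members of the same cytochrome P450 subfamily, only CYP78A9 had a listed probe set. Its log2 level was 6.53 ± 0.04 in WT and 6.53 ± 0.05 in 35S::KLU (SD, n = 3 each), a difference of 0.00 (SE 0.07, limma adjusted p = 0.99). The arrays nevertheless separated by genotype. Correlations across probe sets lay between 0.9952 and 0.9975 within genotypes and between 0.9895 and 0.9931 across them, and the first principal component, with 57.7% of the variance, parted the 3 WT arrays from the 3 35S::KLU arrays. A measure of RNA integrity, the 3′ minus 5′ signal averaged over 3 control genes, was 1.93 ± 0.02 in WT and 1.92 ± 0.03 in 35S::KLU (log2, SD, n = 3 each).

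Cold- and drought-regulated genes and genes of anthocyanin synthesis were among those that rose most in 35S::KLU, and glutaredoxin genes and a cytokinin response regulator were among those that fell most. COR15A, which encodes a cold-regulated chloroplast protein, rose 5.44-fold (log2 8.84 ± 0.16 in WT and 11.29 ± 0.16 in 35S::KLU, adjusted p = 4.2e-06), and its paralog COR15B rose 5.09-fold. DFR, the dihydroflavonol reductase of anthocyanin synthesis, rose 4.85-fold (log2 8.07 ± 0.33 and 10.35 ± 0.43, adjusted p = 2.4e-04). The glutaredoxin gene AT1G06830 was 6.12-fold lower (7.95 ± 0.09 and 5.34 ± 0.23, adjusted p = 4.2e-06). ARR15, a type-A response regulator induced by cytokinin, was 2.63-fold lower (6.87 ± 0.04 and 5.47 ± 0.24, adjusted p = 1.1e-04).

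By limma, 1893 of the 22746 probe sets (8.32%) passed an adjusted p of 0.05, 922 of them higher and 971 lower in 35S::KLU, and 4939 had an unadjusted p under 0.05. Under the 3 other scalings the balance turned, with 971 to 1085 higher and 845 to 924 lower. Of those passing, 172 changed at least 2-fold, 104 upward and 68 downward. With each gene taken by its brightest probe set, 469 genes rose and 446 fell among 13356. The 3 values of each genotype did not overlap for 25.9% of all probe sets, where chance gives 10%. Another 942 of the changed probe sets had no listed gene. The largest difference on the arrays was among these, for probe set 256099_at, which was 27.1-fold higher in 35S::KLU (log2 6.26 ± 0.11 and 11.02 ± 0.06, adjusted p = 2.7e-09). Whether this or another probe set with no listed gene reports KLU itself was not known from the annotation used. Probe set 265058_s_at was 11.6-fold higher, and probe sets 246114_at and 248622_at were 9.34-fold and 5.99-fold lower. The count of changed probe sets was 906 without WT replicate 2, 1236 without WT replicate 3, 1219 without 35S::KLU replicate 2 and 1142 without 35S::KLU replicate 3, each from a fit with 1 array fewer. Weighting the arrays by their quality raised it to 2978.

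**Figure D1:**
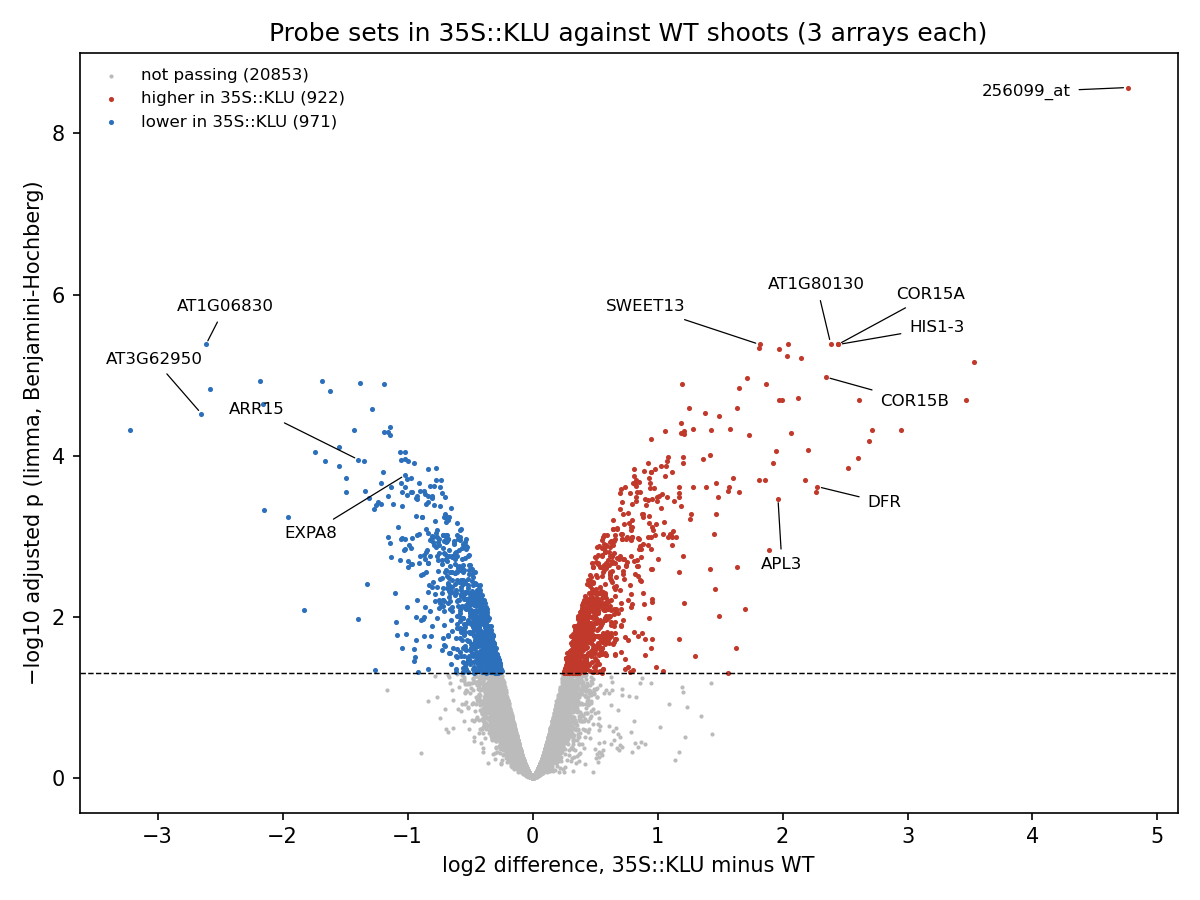
Log2 difference between 35S::KLU and WT (x axis) against the negative log10 of the limma adjusted p (y axis) for each of the 22746 probe sets, red where higher and blue where lower in 35S::KLU at an adjusted p under 0.05 (dashed line). The 922 higher and 971 lower probe sets are shown with 256099_at, which has no listed gene, farthest to the right at 4.76.

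Among genes with a listed probe set, the 10 largest rises ran from 6.55-fold for AT3G53980 to 3.9-fold for APL3, a large subunit of the starch synthesis enzyme ADP-glucose pyrophosphorylase. The others were AT1G52000 (6.06-fold), the drought-inducible linker histone gene HIS1-3 (5.45-fold), COR15A, AT1G80130 (5.22-fold), COR15B, DFR, and the anthocyanin glycosyltransferase genes UF3GT (4.52-fold) and AT4G14090 (4.2-fold). The 10 largest falls ran from at least 6.28-fold for the glutaredoxin gene AT3G62950 to 2.51-fold for AT4G27450. Between them lay AT1G06830, AT3G16670 (3.87-fold), AT2G05540 (3.56-fold), AT5G19120 (3.16-fold), AT2G30600 (2.93-fold), AT1G19450 (2.70-fold), ARR15 and the glutaredoxin gene AT5G18600 (2.54-fold). A second probe set of AT2G30600 gave a log2 difference of -1.34, beside -1.55 for its brightest one. The mean of AT3G62950 in 35S::KLU was 3.45, below the lower quartile of the arrays (4.06 to 4.11), so its fold is a lower bound.

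**Figure D2:**
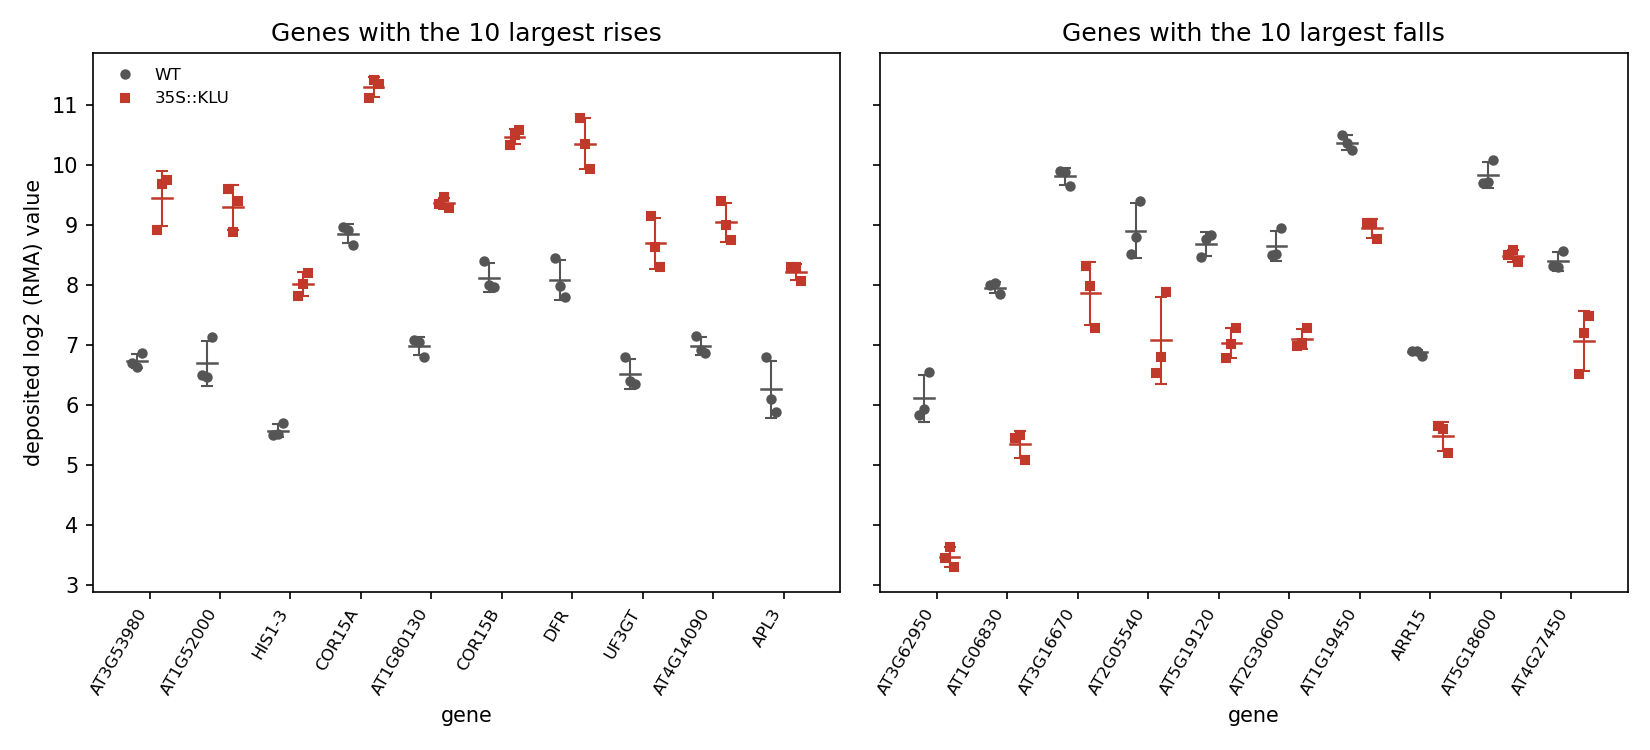
Deposited log2 values of the 10 genes with the largest rises (left) and the 10 with the largest falls (right) on each of the 3 WT (grey circles) and 3 35S::KLU (red squares) arrays, with the mean and SD of each genotype as bars. For each of these genes the values of the genotypes do not overlap.

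The gene lists fixed before the data were examined held 376 members, of which 49 had a listed single-gene probe set, and of these 10 rose, 6 fell and 33 did not pass. Adjusted over the list alone, 11 rose and 9 fell. Members not measured may be reported by probe sets with no listed gene. Of 13 genes of flavonoid and anthocyanin synthesis 3 were measured. All 3 rose (DFR, UF3GT and AT4G14090), and 3 did so adjusted over the list alone. Of 26 genes responding to abscisic acid, drought and cold, 4 were measured and 3 of these rose, with the same count adjusted over the list alone. They were COR15A, COR15B and the dehydrin gene LTI30, which rose 2.75-fold (log2 5.42 ± 0.12 and 6.88 ± 0.58, adjusted p = 0.0045), while COR47 had a log2 difference of 0.10 (SE 0.10, adjusted p = 0.65). Of 3 senescence genes, SAG29 rose 2.25-fold (adjusted p = 2.9e-04), which encodes the sugar transporter SWEET15, and WRKY53 and WRKY6 did not pass, at 0.28 and -0.11 on the log2 scale. In the defence list SAG101, the single member measured, rose 1.42-fold (adjusted p = 0.003). BCAT4, of methionine chain elongation in aliphatic glucosinolate synthesis, rose 1.37-fold (adjusted p = 0.0068), and AT2G31790 of the same list differed by 0.11 (adjusted p = 0.55).

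Both measured cytokinin response genes fell, and both did so adjusted over the list alone. ARR15 fell by 1.39 on the log2 scale, and ARR16, also a type-A response regulator, fell by 0.94 (log2 6.64 ± 0.15 in WT and 5.70 ± 0.55 in 35S::KLU, SE 0.22, adjusted p = 0.031). The call of ARR16 was lost without WT replicate 1, WT replicate 2 or 35S::KLU replicate 2, with adjusted p between 0.073 and 0.12. Of 4 expansin and xyloglucan hydrolase genes, 2 fell, also adjusted over the list alone. EXPA8, a wall-loosening expansin, was 2.03-fold lower (11.01 ± 0.16 and 9.99 ± 0.05, adjusted p = 1.7e-04), and XTH16 was 1.37-fold lower (adjusted p = 0.013), a call lost without WT replicate 2 (adjusted p = 0.058) or 35S::KLU replicate 3 (adjusted p = 0.055). EXPA4 and EXPA15 differed by 0.20 and 0.04 and did not pass. In the touch and wound list EXO fell by 0.62 (adjusted p = 0.0029) and STZ differed by -0.03. In the DNA replication list the gene for MCM7, a subunit of the replicative helicase, was 1.26-fold lower (adjusted p = 0.041), and ICU2 differed by 0.07. The MCM7 call was lost on leaving out any array except 35S::KLU replicate 2, with adjusted p between 0.074 and 0.14.

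The auxin response list was the only fixed list with 5 measured members, and camera found no shift (median log2 difference 0.06, p = 0.33, and p = 0.52 with an estimated correlation). Of its members 1 rose and 0 fell, and adjusted over the list alone 1 rose and 1 fell. The riser was WES1, which encodes the auxin-conjugating enzyme GH3.5, at 1.67-fold (adjusted p = 0.033). Its call was lost on leaving out any array except 35S::KLU replicate 1, with adjusted p between 0.063 and 0.13. IAA29, GH3.3 and LBD29 differed by -0.43, 0.22 and 0.06 and did not pass, though IAA29 passed without 35S::KLU replicate 2 (adjusted p = 0.017). No member passed in the lists of mitosis and cytokinesis (2 of 24 measured, AUR2 -0.18, AUR1 -0.14), organ size regulators (1 of 24, JAG 0.09) and shoot meristem (1 of 10, CLV3 0.09), the values being log2 differences. The same held for heat shock (3 of 12, AT5G37670 0.27, AT1G53540 0.05, ATHSP22.0 0.02) and light harvesting (3 of 20, LHCB4.2 0.13, LHCB4.3 0.22, LHCB4.1 -0.03). It also held for circadian clock (1 of 14, GI -0.17), cuticle (1 of 20, WSD1 -0.15) and jasmonate (1 of 18, PDF1.2 0.14). So few members do not speak for a whole list. The means of CLV3, WSD1 and AT1G53540 also lay below the arrays' lower quartile (4.06 to 4.11), where changes are understated. Nor did a member pass among cytosolic ribosomal proteins (AT2G19730 -0.29, AT3G09630 -0.29), though both fell adjusted over the list alone and AT3G09630 passed without WT replicate 1 (adjusted p = 0.039). In the iron deficiency list PYE differed by 0.40 and BHLH101 by 1.17 with an SD of 2.03 in WT, and neither passed. Without WT replicate 3 BHLH101 differed by 0.01, and without WT replicate 1 PYE passed (adjusted p = 0.021). Among markers of root tissue, EXPA7 and EXPA18 differed by -0.17 and -0.07, and PYK10 by 0.43 (adjusted p = 0.078), which passed adjusted over the list alone and without WT replicate 3 (adjusted p = 0.019). Of the 12 members of the floral list 0 had a listed probe set.

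Of 25 further lists tested, drawn up after the annotation had been seen and before any difference was computed, camera with its preset correlation found 4 shifted, 1 toward higher and 3 toward lower values in 35S::KLU, and with an estimated correlation 0 were. Dehydrin, late embryogenesis abundant (LEA) and cold-regulated genes were higher, with a median log2 difference of 0.44 (adjusted p = 7.9e-09, and adjusted p = 0.4995 with an estimated correlation). Of 15 members 6 rose and 0 fell, and the count was the same adjusted over the list alone. Beside COR15A, COR15B and LTI30 these were XERICO (1.49-fold, adjusted p = 0.0026), RD2 (1.35-fold) and DI19 (1.43-fold). Whether XERICO, RD2 and DI19 belong to the classes that name the list was not checked. The median was 0.20 without 35S::KLU replicate 2, and the calls of RD2 and DI19 were lost without that array, 35S::KLU replicate 3 or WT replicate 2, with adjusted p up to 0.067 and 0.085.

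Xyloglucan endotransglucosylase/hydrolase (XTH) genes, which remodel the cell wall, were lower (median -0.14, adjusted p = 0.018, and adjusted p = 0.4995 with an estimated correlation). Of 10 members 3 fell and 0 rose, and 4 fell adjusted over the list alone. XTH19 was 2.00-fold lower (log2 6.72 ± 0.17 and 5.72 ± 0.29, adjusted p = 0.0024) and EXGT-A3 1.62-fold lower (10.25 ± 0.03 and 9.55 ± 0.10, adjusted p = 5.3e-04). Without 35S::KLU replicate 1 the list's adjusted p was 0.06.

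Cytosolic ribosomal protein genes were lower as a list of 89 (median -0.24, adjusted p = 1.1e-12, and adjusted p = 0.566 with an estimated correlation), while 5 members fell, 0 rose and 84 did not pass. Adjusted over the list alone, 0 passed. The median lay between -0.23 and -0.20 under the other scalings, and it was -0.14 without WT replicate 3. The 5 genes that fell were AT3G16780 (-0.48), AT4G30800 (-0.39), AT3G13580 (-0.35), AT5G15520 (-0.32) and AT3G02080 (-0.28), and each lost its call on leaving out at least 4 of the 6 arrays in turn, with adjusted p up to 0.16. All except AT3G16780 also lost it under at least 1 of the other scalings. Array signals of plastid-encoded genes of ribosomal proteins and RNA polymerase were also lower (median -0.22, adjusted p = 3.1e-04, and adjusted p = 0.556 with an estimated correlation). Whether these signals follow the abundance of plastid transcripts was not checked. Of 19 members 2 fell and 0 rose, in both adjustments. They were rps16 (1.68-fold, adjusted p = 0.0077) and rpl16 (1.53-fold, adjusted p = 0.018), the second losing its call without WT replicate 2 (adjusted p = 0.087) or 35S::KLU replicate 3 (adjusted p = 0.061). The median was -0.12 without 35S::KLU replicate 2.

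**Figure D3:**
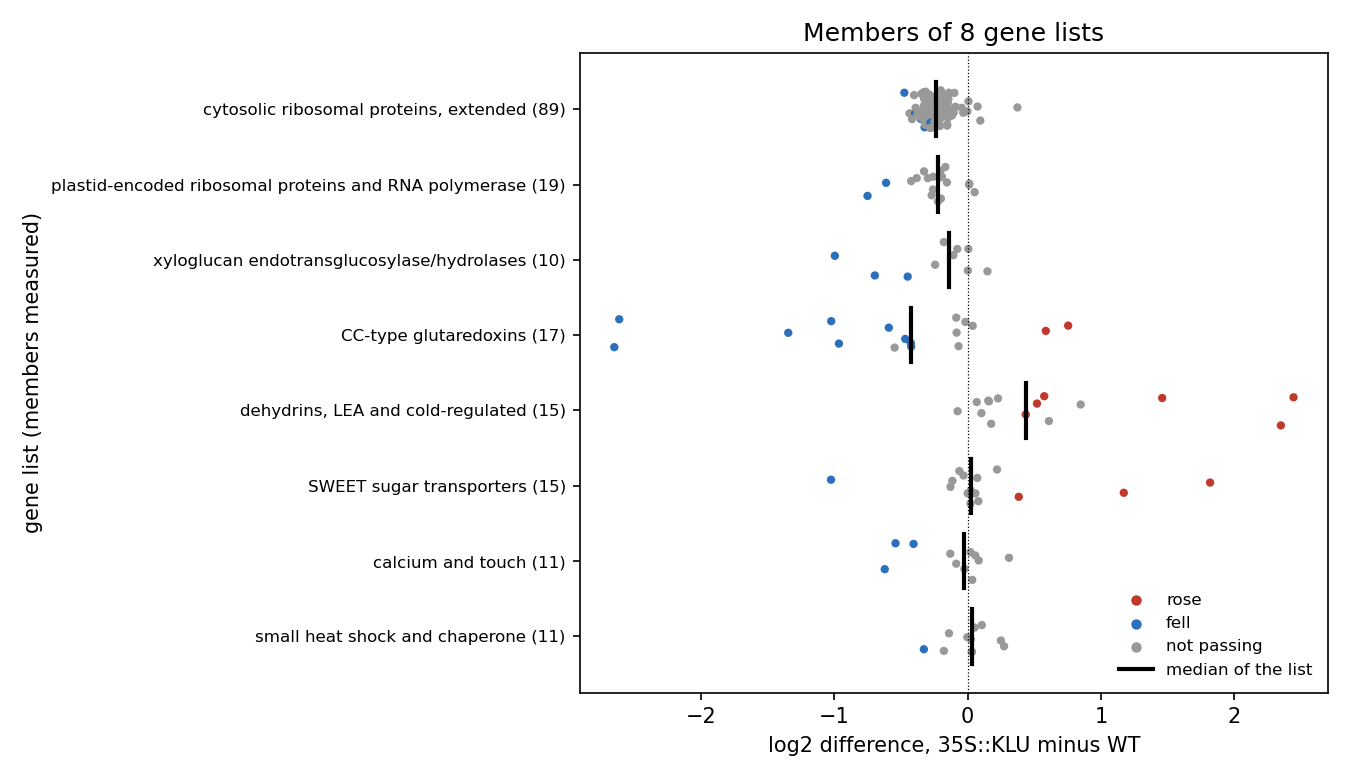
Log2 difference between 35S::KLU and WT (x axis) of each measured member of 8 gene lists (rows, with the number measured), coloured by whether the gene rose, fell or did not pass at an adjusted p under 0.05, with the median of each list as a black bar. The medians run from -0.43 for the glutaredoxins, a list drawn up after their largest falls had been seen, to 0.44 for the dehydrin, LEA and cold-regulated genes.

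Camera found no shift in the other 21 lists over all 6 arrays, some of which held strongly changed members. Of 15 SWEET sugar transporter genes 3 rose and 1 fell, also adjusted over the list alone (median 0.02, adjusted p = 0.11). SWEET13, a sucrose transporter gene, rose 3.52-fold (log2 5.99 ± 0.08 and 7.81 ± 0.09, adjusted p = 4.2e-06), and SWEET2 was 2.04-fold lower (8.23 ± 0.03 and 7.21 ± 0.31, adjusted p = 0.0015). SWEET16 rose too, a call lost without WT replicate 2, 35S::KLU replicate 2 or 35S::KLU replicate 3, with adjusted p up to 0.07. In a list of 47 UDP-glycosyltransferase genes, all with symbols beginning in UGT, 5 rose and 1 fell. The counts were the same adjusted over the list alone (median 0.03, adjusted p = 0.11). Glycosyltransferase genes with other names were left out, among them UF3GT (4.52-fold) and AT4G14090 (4.2-fold), which rose, and AT2G31790, which did not pass. The flavonoid 3-O-glucosyltransferase gene UGT78D2 rose 2.01-fold (7.94 ± 0.07 and 8.95 ± 0.31, adjusted p = 0.0019), and the cytokinin N-glucosyltransferase gene UGT76C2 was 2.07-fold lower (7.67 ± 0.05 and 6.62 ± 0.29, adjusted p = 0.0011). The calls of the risers UGT78D1 and UGT73B5 were lost without WT replicate 2, and that of UGT73B5 also without 3 other arrays, with adjusted p up to 0.071 and 0.097. Of 18 expansin genes 2 rose (EXLB1 1.72-fold, EXPB3 1.55-fold) and 2 fell (EXPA8, and EXLA1 1.62-fold), while 2 rose and 4 fell adjusted over the list alone (median -0.03, adjusted p = 0.76). EXPB3 lost its call without WT replicate 2 (adjusted p = 0.052). Of 14 glutathione transferase genes 2 rose, GSTU26 (1.77-fold) and GSTU20 (1.32-fold), and 1 fell, while 3 rose and 1 fell adjusted over the list alone (median -0.003, adjusted p = 0.22), and the list passed with the filter on dim probe sets (median 0.24, adjusted p = 0.042). The 1 that fell, GSTF4 (adjusted p = 0.047), lost its call on leaving out any array, with adjusted p between 0.058 and 0.11. Of 11 calcium and touch genes 3 fell, among them CML30 (1.46-fold) and EXO, and 0 rose (median -0.03, adjusted p = 0.28), while 1 rose and 3 fell adjusted over the list alone. The third, CML42, lost its call without WT replicate 2 or 35S::KLU replicate 3, with adjusted p up to 0.062. Of 28 genes in the core histone list 9 were measured, all of them genes of histone H2B. Of these 2 fell, AT2G37470 (1.4-fold) and AT3G53650 (1.28-fold), in both adjustments (median -0.08, adjusted p = 0.11). AT3G53650 lost its call under each of the 3 other scalings, with adjusted p up to 0.068, and without any array except WT replicate 1, with adjusted p up to 0.18.

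In the remaining lists few members changed. Of 19 CYP71B cytochrome P450 genes CYP71B26 and CYP71B6 rose (1.39-fold and 1.41-fold) and 1 fell, while 3 rose and 1 fell adjusted over the list alone (median 0.06, adjusted p = 0.074). The list passed without 35S::KLU replicate 2 (adjusted p = 0.018) and with the filter on dim probe sets (median 0.15, adjusted p = 0.028), and the call of CYP71B22, which fell, was lost without any array except WT replicate 3 (adjusted p up to 0.18) and under 1 other scaling. Of 26 plastid-encoded photosystem and cytochrome b6f genes 3 fell, psbB (1.47-fold), petN (1.35-fold) and petL (2.40-fold), in both adjustments (median -0.10, adjusted p = 0.19). The list passed without 35S::KLU replicate 1 (median -0.16, adjusted p = 0.0068), and its median was -0.02 without 35S::KLU replicate 2 (adjusted p = 0.49). The petN call was lost without WT replicate 2 (adjusted p = 0.06), and the petL call was lost without WT replicate 1, WT replicate 2, 35S::KLU replicate 2 or 35S::KLU replicate 3, with adjusted p up to 0.17. Of 25 cell division genes 1 fell, the MCM7 gene above, and 0 passed adjusted over the list alone (median -0.07, adjusted p = 0.10), though the list passed without 35S::KLU replicate 2 (adjusted p = 0.03), and its median was -0.03 without 35S::KLU replicate 3 (adjusted p = 0.28). Of 7 tubulin genes 0 passed in either adjustment (median -0.10, adjusted p = 0.21), but the list passed without 35S::KLU replicate 2 (median -0.17, adjusted p = 0.025), and its median was -0.04 without 35S::KLU replicate 1 (adjusted p = 0.75). Of 20 leaf polarity and organ shape genes NGA1 rose and ULT1 fell, in both adjustments (median 0.01, adjusted p = 0.34). Each of these calls was lost without 35S::KLU replicate 1, with adjusted p of 0.079 and 0.089, and without several other arrays. Of 28 nuclear photosynthesis genes the protochlorophyllide oxidoreductase gene PORB rose 1.38-fold, in both adjustments (median -0.06, adjusted p = 0.44), a call lost without WT replicate 2 (adjusted p = 0.10) or 35S::KLU replicate 3 (adjusted p = 0.052). Of 23 defence genes 2 rose and 0 fell, while 2 rose and 1 fell adjusted over the list alone (median -0.09, adjusted p = 0.89).

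Of 22 TBL wall acetylation genes 2 fell, among them TBL45 (1.61-fold), in both adjustments (median -0.03, adjusted p = 0.69). The other, TBL37, lost its call on leaving out 4 of the 6 arrays in turn, with adjusted p up to 0.083. Of 21 beta-glucosidase genes BGLU25 rose and BGLU16 fell (median 0.01, adjusted p = 0.44), and of 15 tetraspanin genes TET10 fell (median 0.04, adjusted p = 0.44), with the same counts adjusted over the list alone. All 3 calls were lost without WT replicate 2 or 35S::KLU replicate 3 and without at least 1 further array, with adjusted p up to 0.13, 0.086 and 0.10, and that of BGLU25 also under median-centring. Of 11 small heat shock and chaperone genes Hop1 fell, in both adjustments (median 0.03, adjusted p = 0.86), a call lost without any array except WT replicate 1, with adjusted p up to 0.098. Of 19 auxin synthesis and response genes WES1 rose, and 2 rose adjusted over the list alone (median -0.01, adjusted p = 0.87). Of 10 plastid-encoded NDH genes and 16 mitochondrially encoded genes 0 passed in either adjustment (medians -0.05 and 0.02, adjusted p = 0.86 and 0.97). The 4 measured genes of the stomatal lineage, too few for a list test, did not pass, from -0.25 for MUTE to 0.07 for STOMAGEN. For the glutathione transferase, auxin and mitochondrial lists the median, the mean and the direction given by camera differed in sign. The self-contained test fry, which asks whether the genes of a list moved on balance one way, passed for 5 of the 25 lists. The dehydrin, XTH and core histone lists passed (adjusted p = 0.027 each), the last measured by H2B genes alone. So did the SWEET list (adjusted p = 0.0082) and the calcium and touch list (adjusted p = 0.046). The ribosomal lists did not pass by fry (adjusted p = 0.19 for both).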

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

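The added gene lists were an alternative chosen after seeing the annotation, and the glutaredoxin list without 3 members one chosen after seeing the data; all other settings were planned. The 1893 changed probe sets (922 higher, 971 lower) became 2978 (1433 and 1545) with array weights, for which the cause was not tested, 789 (398 and 391) at an adjusted p under 0.01, 602 (315 and 287) with a fold of at least 1.5, and 836 (430 and 406) with 1 probe set per gene, the last 3 being smaller by construction. Leaving out 1 array gave 906 to 1962 (447 to 1030 higher, 459 to 932 lower), each from fewer samples. The replicate block gave 1279 (632 and 647), and deviations of samples with the same number correlated at -0.205, 0.039 and -0.056, those with different numbers at -0.154 to 0.21, and only WT replicate 2 correlated best with its own number, a hint from the data that leaves the pairing open. Other scalings gave 1895 to 1930 (971 to 1085 higher, 845 to 924 lower), which turned the majority from lower to higher, moved the share of higher calls by at most 7.51 percentage points and the median of all probe sets by at most 0.0161. The 4 added lists called by camera became 0 with an estimated correlation, with or without the replicate block, and 4 to 7 without 1 array, 7 of them without 35S::KLU replicate 2, where the CYP71B, cell division and tubulin lists passed as well; the cause was not tested. The list of plastid-encoded photosystem and cytochrome b6f genes passed without 35S::KLU replicate 1, and the CYP71B and glutathione transferase lists with the filter on dim probe sets, which left the XTH and glutaredoxin lists too small to test. The glutaredoxin list's adjusted p with an estimated correlation, 0.0092, was 0.061 with the replicate block and 0.077 without the 3 members seen beforehand. The count for the fixed lists stayed at 0 wherever it was run, and the filter on dim probe sets could not be run for it. Of 120 genes followed, 88 passed and 0 reversed while called, but 11 changed sign in some setting without a call, GI, LHCB4.3 and PDF1.2 among them. Of the 88, 15 lost the call with the block, 7 under another scaling or array weights, and 33 without at least 1 array. Of the genes that did not pass, 4 passed in some setting, IAA29, PYK10, PYE and AT3G09630, each without 1 array and with array weights, and PYK10 also with the replicate block. The 20 largest rises and falls lost 0 calls in these settings. The targeted gene was not run. Signal over background limits probe sets near the floor of about 3 to 4.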

Other observations

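The gene lists of glutaredoxins and of dark- and starvation-induced genes were drawn up after the largest differences had been seen. The test of RNA integrity was chosen only after its values were seen. The other tests, except 1 named below, were set before their results were seen, but the bound for sugar status was read with an added condition, given below. Of 17 plant-specific CC-type glutaredoxin genes measured, 9 fell in 35S::KLU, 2 rose and 6 did not pass, and adjusted over the list alone 10 fell and 2 rose (median -0.43, camera adjusted p = 2.1e-07, and adjusted p = 0.0092 with an estimated correlation). In a test added after the data were seen, of the 14 members left without the 3 seen beforehand 6 fell, 2 rose and 6 did not pass. Their median was -0.25, and the list passed by camera (adjusted p = 0.0023) and fry (adjusted p = 0.0035) but not with an estimated correlation (adjusted p = 0.077). Of the 6 that fell, AT4G15660, AT4G15680, AT4G15690 and AT4G15700 have close locus numbers, and AT3G62930 is close to AT3G62950, seen beforehand. Whether these members fell independently was not tested, and camera's preset correlation of 0.01 treats members as nearly independent. Beside AT3G62950, AT1G06830 and AT5G18600, which had been seen beforehand, AT4G15690 was 2.03-fold lower (log2 5.15 ± 0.30 and 4.12 ± 0.07, adjusted p = 0.0015), AT4G15700 was at least 1.95-fold lower, AT4G15680 1.51-fold, ROXY2 1.38-fold, AT3G62930 1.34-fold, and AT4G15660 at least 1.34-fold. The call of ROXY2 was lost without WT replicate 2 (adjusted p = 0.065). AT4G33040 rose 1.69-fold and AT5G11930 1.5-fold, the second losing its call without WT replicate 2 or any 1 of the 35S::KLU arrays (adjusted p up to 0.098). The means of AT3G62950, AT4G15700 and AT4G15660 in 35S::KLU lay between 3.04 and 3.45, below the arrays' lower quartile, so their folds are lower bounds.

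The fall of the glutaredoxin genes was weighed against probe sets shared between paralogous glutaredoxin genes and a lower cytokinin response. Of the 9 probe sets that fell, 0 were of the kind that Affymetrix marks as shared between transcripts, but the bound set beforehand was wrong, because only 2.09% of all single-gene probe sets are of that kind (84.1% of several-gene ones), so shared probes stay open. The other listed type-A response regulator, ARR16, fell by 0.94 (log2), as a lower cytokinin response would predict, but its call was lost without any 1 of 3 arrays. The falls of ARR15 and ARR16 bear on the cytokinin response only, and no test linked it to the glutaredoxin genes, so that it lowered them is an untested hypothesis. The other cytokinin genes of the fixed list were not analysed here.

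All 3 measured anthocyanin genes and 6 of the 15 members of the dehydrin, LEA and cold-regulated list rose. By camera with an estimated correlation the dehydrin list did not pass (adjusted p = 0.4995). Whether XERICO, RD2 and DI19, which are among the 6, belong to the classes that name it was not checked. Handling or heat stress at harvest and a higher sugar status were weighed as explanations. Calcium and touch genes had a median log2 difference of -0.025 (95% bootstrap interval over members -0.406 to 0.0569). Of these 11 genes 3 fell and 0 rose, and fry passed for the list (adjusted p = 0.046). Small heat shock and chaperone genes had a median of 0.0309 (-0.14 to 0.106). The intervals hold the spread over genes and not over arrays. Neither list rose, which argues against handling or heat stress at harvest that raises these genes. The means of CML23, CML37 and CML38 lay below the arrays' lower quartile, where changes are understated. Of the fixed touch and wound list 2 of 15 members were measured, and of the heat shock list 3 of 12. Stress that acts on unmeasured members stays open. Genes induced in the dark or by sugar starvation had a median of 0.0786 (-0.333 to 0.129, fry p = 0.648), with 2 of 10 falling (AKINBETA1 by 0.66 and AT3G15450 by 1.09, with adjusted p = 0.055 without WT replicate 2), 3 adjusted over the list alone, and camera adjusted p = 0.93 (0.96 with an estimated correlation), the median and mean differing in sign. The bound set beforehand against a higher sugar status, a median above 0, was met. A condition on the interval, not written beforehand, was added, because the bound left out the spread over members. The interval reaches below 0, and of the members that passed 2 fell and 0 rose, so a higher sugar status stays open. The genotype itself stays open as an untested explanation.

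For the count of changed probe sets, 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1893 changed probe sets and the highest of the others 0, and 1 of the 10 reached the real count. RNA integrity, read from 3 control genes, differed between the genotypes by -0.006 (log2), with overlapping arrays. These control genes showed no difference in integrity. Because the test was chosen after its values were seen, it cannot exclude RNA integrity as a cause of these changes.

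Of the 64 control probe sets left out of the comparison, 1 passed, for a spiked-in phe transcript that was lower in 35S::KLU by limma (log2 difference -0.27, adjusted p = 0.049). In a tally added after these values were seen, 22 of the 24 probe sets of the spiked-in dap, lys, phe and thr transcripts were lower in 35S::KLU (median -0.101), 6 of them with an unadjusted p under 0.05. Several of these probe sets report the same transcript, and the cause was not tested.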
